A study of Danio rerio with 20 samples.

How the data were processed

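RNA was measured in whole zebrafish larvae of the Tg(fli1:EGFP) line, which carries green fluorescent protein in endothelial cells. The 20 libraries fell into 4 genotypes with 5 libraries each: wild type, aldh3a1 knockout, glo1 knockout and the double knockout. The larval age was not given in the sources used here. Per the labels' protocols, RNA was extracted with a column kit and made into strand-specific mRNA libraries for DNBSEQ sequencing. The deposited values are whole-number counts per gene. Per the submitters' processing notes, featureCounts 2.0.3 made the counts and the build was GRCz11. The aligner, the annotation and the strand setting of the counting were not given in the sources used here, so antisense and overlapping genes cannot be told apart with certainty. Reads of near-identical paralogs may also be shared, which concerns the crystallin, actin, digestive enzyme and complement genes named in the report.

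The table held 32520 gene IDs. A symbol was matched to 29201 of them through a table of gene IDs and symbols, and 6314 IDs shared a symbol with another ID. Such genes are printed with their ID. The symbols of the fixed gene lists were matched exactly, then through synonyms in a RefSeq gene table of assembly GRCz12tu, then by their stem without a paralog suffix. The matching by stem was chosen after the files were opened and before any expression value was compared. The GRCz12tu table was used for names and for the order of neighbouring genes. No ID carried the symbol aldh3a1, and counts of that gene, which would check the aldh3a1 label, were not analysed here.

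Totals ranged from 35092716 to 37190519 counts per library. After filterByExpr by genotype, 22234 genes were tested, which held 99.97% of the counts. One model over the 20 libraries was fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersion estimation and the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.130. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the root of the F statistic. All adjusted p-values of genes in the report come from this test. The 6 comparisons were each knockout and the double knockout against wild type, the double knockout against each single knockout, and the interaction (the change in the double knockout minus the sum of both single changes on the log2 scale). The 36 gene lists, the designs, the other settings tried and the rule for naming genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 36 lists of a comparison. CPM values (counts scaled to the library size) were computed from the deposited counts with TMM factors.

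The naming rule took glo1 and aldh3a1, then the 10 genes in each direction with the largest change in comparisons with wild type and 5 in each direction in the others. These had to pass the test, have a mean of at least 5 CPM in the higher group and, except for the interaction, show no overlap between the groups' libraries. Clone names were left out. For each list that was called or held at least 3 called genes in a comparison with wild type, up to 4 members with the smallest adjusted p were added. The rule named 316 genes, and all of them entered the alternatives. For length, and to keep the account of single libraries that stand apart short, the text prints at most 2 of these members per list, in the rule's order, for called lists and for the lists on the proteasome, vessels and glucose that the series title points to. This shortening was chosen after values were seen.

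Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with sample quality weights, other filters, a fit without robust estimation, the replicate number as a block, fits on the compared genotypes alone, a fold threshold, each library left out in turn, and other list tests. On simulated counts for the aldh3a1 comparison over 22234 genes, with real means and library sizes, 52% of genes changed 1.5-fold, 78% of genes changed 2-fold and 96% of genes changed 4-fold were recovered, with 5 false calls. For the interaction over 22234 genes, 36% of genes changed 1.5-fold and 90% of genes changed 4-fold were recovered. The simulations changed 50 genes at each fold. Fewer changed genes make the adjusted threshold stricter, so recovery among the many changes of the real data was not measured. Figures were drawn with matplotlib 3.10.9. The labels do not say that the libraries came from separate clutches or pools, so p-values measure the spread between these libraries, which may be technical.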

Results

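Gene expression was measured in zebrafish larvae that lacked glo1, aldh3a1 or both, and in wild type larvae. Glo1 encodes glyoxalase 1, which detoxifies methylglyoxal, and ALDH3A1 is an aldehyde dehydrogenase. The series title links the double knockout to a methylglyoxal adduct, the small vessels, glucose metabolism and proteasome activity. Each genotype had 5 libraries, with 35092716 to 37190519 counts per library. The first principal component held 43.2% of the variance and separated wild type from the aldh3a1 knockout. The glo1 knockout lay between them, and the double knockout overlapped the aldh3a1 knockout on this axis, its replicates 4 and 5 (29.3 and 33.9) lying beyond aldh3a1 knockout replicate 2 (27.2). The second component held 11.2% and separated the genotypes with a glo1 knockout from the others. The glo1 and double knockouts lay from -32.6 to -11.6 on it, and wild type and the aldh3a1 knockout from 9.4 to 34.9.

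**Figure D1:**
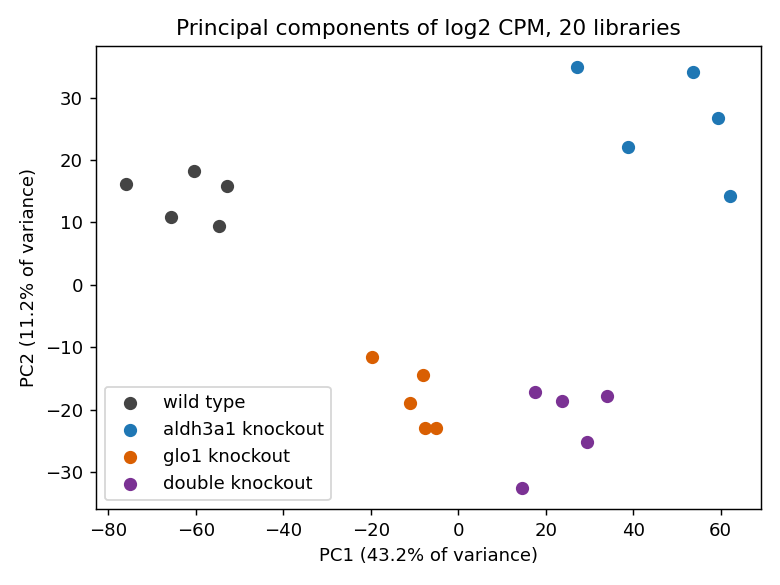
First 2 principal components of log2 CPM over 22234 genes, one point per library and one colour per genotype. The 5 libraries of each genotype lie together, and the axes hold 43.2% and 11.2% of the variance.

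The targeted glo1 transcript was measured at 66.6 ± 3.88 CPM in wild type, 78.5 ± 2.85 in the aldh3a1 knockout, 3.66 ± 0.345 in the glo1 knockout and 4.30 ± 0.724 in the double knockout (SD, n = 5 each). It fell by 4.19 on the log2 scale in the glo1 knockout (SE 0.09, edgeR adjusted p = 7.76e-22) and by 3.95 in the double knockout (SE 0.09, edgeR adjusted p = 2.24e-21). In the aldh3a1 knockout glo1 was higher by 0.24 (SE 0.07, edgeR adjusted p = 0.00640). The double and glo1 knockouts did not pass the test for glo1 (log2 fold change 0.23, SE 0.09, edgeR adjusted p = 0.111), and the value was 0.31 without double knockout replicate 1 (edgeR adjusted p = 0.0261) and 0.14 without double knockout replicate 5 (edgeR adjusted p = 0.361). Counts of aldh3a1 itself were not analysed here.

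**Figure D2:**
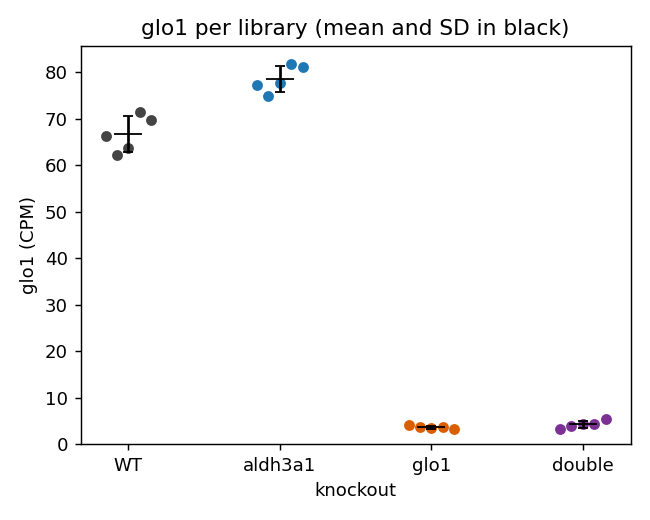
CPM of glo1 in each of the 20 libraries by genotype, with the mean and SD in black and the axis starting at 0. All libraries of the glo1 and double knockouts lie between 3.28 and 5.35 CPM, and all others between 62.2 and 81.7 CPM.

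The first comparison asked how loss of aldh3a1 changed the larval transcriptome. Liver, gut, exocrine pancreas and muscle genes were lower and ribosomal protein genes were higher. Of 39 liver genes, 37 fell and 0 rose, with a median log2 fold change of -1.54. They included f2, which encodes prothrombin (-1.43, SE 0.15). Adjusted over the list alone, 37 passed (camera adjusted p = 2.25e-13; adjusted p = 0.477 with an estimated correlation). Of 33 enterocyte and lipid transport genes, 27 fell and 0 rose, and 28 passed adjusted over the list alone (median -1.58, camera adjusted p = 1.14e-06; adjusted p = 0.613 with an estimated correlation). Among them were slc6a19 (ENSDARG00000056719), an amino acid transporter (-2.10, SE 0.24), and cdx1b, an intestinal transcription factor (-1.04, SE 0.14). Exocrine pancreas genes had a median of -1.80, with 24 of 29 lower and 1 higher and 26 adjusted over the list alone (camera adjusted p = 0.000323; adjusted p = 0.699 with an estimated correlation). The chymotrypsin gene ctrb.2 fell by 2.98 (SE 0.45).

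Skeletal muscle genes fell in 63 of 74 cases and rose in 3, with 67 passing adjusted over the list alone (median -0.86, camera adjusted p = 6.53e-16; adjusted p = 0.477 with an estimated correlation). The calcium release channel gene ryr1 (ENSDARG00000023797) fell by 2.07 (SE 0.12) and ryr3 by 1.78 (SE 0.11). Heart muscle genes were lower in 17 of 21 cases and higher in 0, with 17 adjusted over the list alone (camera adjusted p = 0.00694; adjusted p = 0.477 with an estimated correlation), among them the natriuretic peptide gene nppa (-1.91, SE 0.26). Extracellular matrix and cartilage genes fell in 38 of 63 cases and rose in 7, with 45 adjusted over the list alone (camera adjusted p = 0.000126; adjusted p = 0.699 with an estimated correlation), and the basement membrane collagen col4a1 fell by 2.68 (SE 0.18). Of 90 ribosomal protein genes, 82 rose and 5 fell, and 87 passed adjusted over the list alone (median 0.64, camera adjusted p = 3.37e-34; adjusted p = 0.477 with an estimated correlation). They included rpl9 (0.99, SE 0.06) and rplp2 (1.15, SE 0.08). The 13 mitochondrially encoded genes rose in 11 cases and fell in 2, with 13 adjusted over the list alone (camera adjusted p = 1.61e-05; adjusted p = 0.477 with an estimated correlation). In the same comparison, of 79 genes of very long proteins matched from 108 listed, 35 fell and 12 rose, with a median of -0.11 against 0.14 for random lists matched on expression. The share of counts of the mitochondrially encoded genes was 3.93% ± 0.230 against 2.88% ± 0.232 in wild type (SD, n = 5 each).

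Among the lists on glucose, 2 were called lower in the aldh3a1 knockout. Of 33 gluconeogenesis and glycogen genes, 22 fell and 3 rose, with 26 adjusted over the list alone (median -0.87, camera adjusted p = 1.61e-05; adjusted p = 0.477 with an estimated correlation). The glycogen phosphorylase gene pygb fell by 0.97 (SE 0.08). Of 42 insulin signalling and glucose transport genes, 20 fell and 6 rose, with 26 adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.477 with an estimated correlation), and the glucose transporter gene slc2a1 (ENSDARG00000007412) fell by 1.89 (SE 0.16). The 34 dicarbonyl and aldehyde detoxification genes held 18 lower and 4 higher members, 22 adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.699 with an estimated correlation). That call was lost without aldh3a1 knockout replicate 3 (adjusted p = 0.0509) or wild type replicate 1 (adjusted p = 0.0523). Glycolysis, endocrine pancreas and endothelium lists did not pass (camera adjusted p = 0.717, 0.422 and 0.721), although the vessel guidance receptor gene nrp1b fell by 1.51 (SE 0.14). Camera compares a list with the other genes, so a list that does not pass is not thereby unchanged. The mean log2 CPM of the glycolysis list relative to wild type was -0.46 to -0.19 in the aldh3a1 knockout libraries. In the wild type libraries it was -0.10 to 0.06. The endocrine pancreas list had a median of 0.14 and a mean of -0.01, and the endothelium list a median of 0.00 and a mean of -0.17. By fry, the endocrine pancreas list was called higher (adjusted p = 0.00505) and the endothelium list lower (adjusted p = 0.00212). Among 46 constitutive proteasome genes, 20 rose and 5 fell, with 22 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.292). The psmd2 copy ENSDARG00000103190 fell by 1.85 (SE 0.12), while psma1 rose by 0.53 (SE 0.05).

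Among the genes named by the rule, the largest rises in the aldh3a1 knockout were those of tnfrsf14, a receptor of the tumour necrosis factor family (3.58, SE 0.31), and ctsb, which encodes cathepsin B (2.26, SE 0.39). The potassium channel gene kcna7 fell by 4.63 (SE 0.37), and the muscle cadherin gene cdh15 fell by 3.88 (SE 0.37). The sarcomere gene myom1 (ENSDARG00000104836) fell by 3.86 (SE 0.31) and obscnb, another sarcomere gene, fell by 3.42 (SE 0.26). In all, 13637 of 22234 genes passed the edgeR test, 6527 higher and 7110 lower. With a change of at least 1 on the log2 scale, 512 were higher and 3040 lower. Camera called 16 of the 36 lists, 5 higher and 11 lower, and 0 with an estimated correlation, against 24 by fry. List counts of this size were also common when the libraries were regrouped at random, 44 of 100 groupings giving as many, so the list count by itself does not set the genotypes apart.

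**Figure D3:**
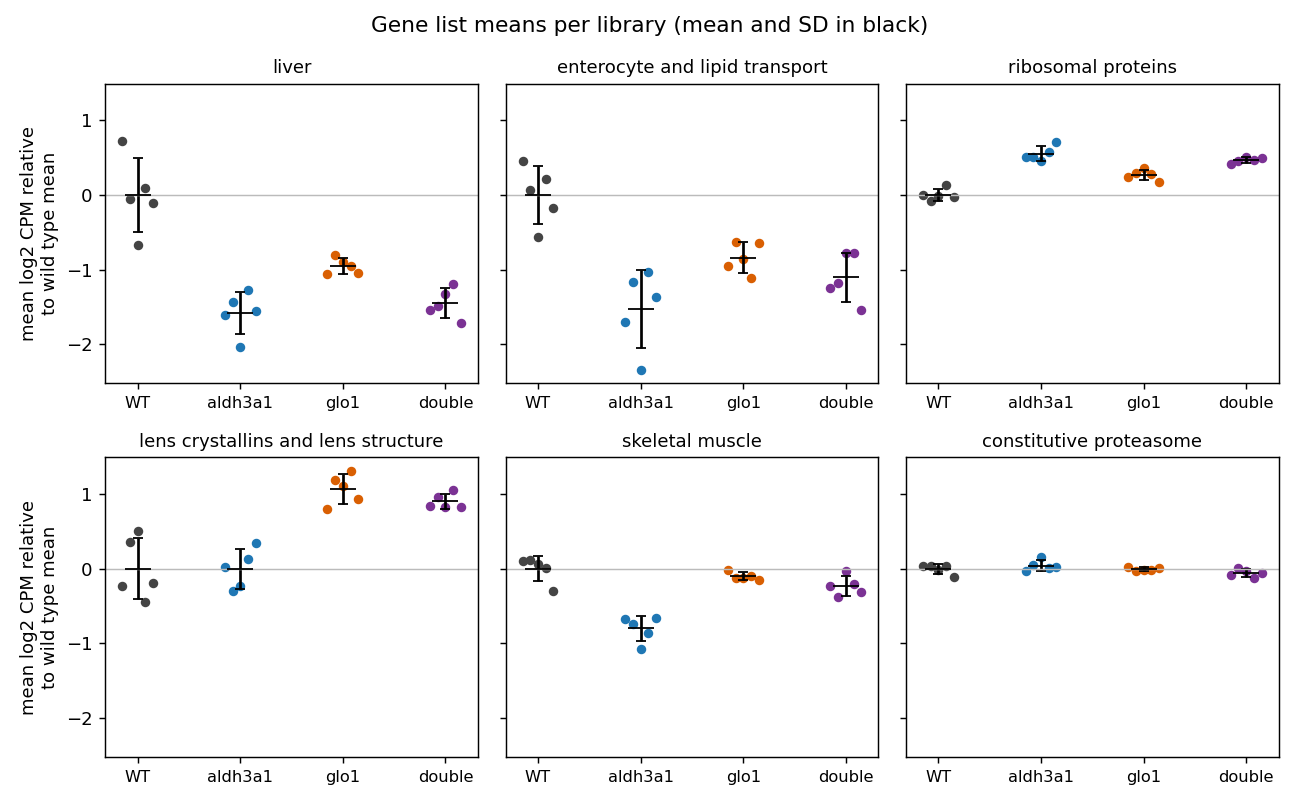
Mean log2 CPM of 6 gene lists in each of the 20 libraries, relative to the wild type mean, with the genotype mean and SD in black. Liver means were -1.58 in the aldh3a1 knockout, -0.95 in the glo1 knockout and -1.45 in the double knockout, lens means were 1.07 in the glo1 knockout and 0.90 in the double knockout, and proteasome means stayed between -0.06 and 0.04.

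The second comparison asked what loss of glo1 changed. Lens genes were higher: 50 of 57 lens crystallin and lens structure genes rose and 0 fell, with a median of 1.08 and 51 adjusted over the list alone (camera adjusted p = 2.20e-39; adjusted p = 0.222 with an estimated correlation). The crystallin gene crygmxl1 rose by 1.70 (SE 0.21) and the galectin-related lens gene grifin by 0.96 (SE 0.11). Of 39 liver genes, 34 fell and 0 rose, 36 adjusted over the list alone (median -1.03, camera adjusted p = 4.42e-16; adjusted p = 0.500 with an estimated correlation), including the complement gene c3a.1 (-1.23, SE 0.18). Enterocyte and lipid transport genes fell in 25 of 33 cases and rose in 0, with 27 adjusted over the list alone (median -0.92, camera adjusted p = 2.50e-07; adjusted p = 0.597 with an estimated correlation), including mttp, which loads lipoproteins (-0.82, SE 0.17). Ribosomal protein genes rose in 74 of 90 cases and fell in 2, with 78 adjusted over the list alone (median 0.30, camera adjusted p = 3.13e-24; adjusted p = 0.500 with an estimated correlation). The 79 genes of very long proteins had a median of -0.07 against 0.06 for matched random lists, with 19 lower and 3 higher. Of 13 mitochondrially encoded genes, 6 rose and 0 fell, with 8 adjusted over the list alone (camera adjusted p = 0.00179; adjusted p = 0.597 with an estimated correlation), and their share of counts was 3.27% ± 0.0831 (SD, n = 5).

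Phototransduction genes rose in 39 of 82 cases and fell in 2 in the glo1 knockout, with 44 adjusted over the list alone (camera adjusted p = 2.29e-11; adjusted p = 0.222 with an estimated correlation), among them rlbp1a (0.68, SE 0.06). The phototransduction list was also called higher in the aldh3a1 knockout (camera adjusted p = 0.000126, or 0.477 with an estimated correlation). So it was in the double knockout (camera adjusted p = 1.19e-05, or 0.784 with an estimated correlation). Its means relative to wild type were 0.26 in the aldh3a1, 0.30 in the glo1 and 0.27 in the double knockout. The dicarbonyl and aldehyde list held 14 lower and 2 higher genes of 34, with 16 adjusted over the list alone (camera adjusted p = 1.01e-05; adjusted p = 0.500 with an estimated correlation). This list contains glo1 itself, and aldh4a1 fell by 0.57 (SE 0.09). Gluconeogenesis and glycogen genes were lower in 16 of 33 cases and higher in 2, 24 adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.597 with an estimated correlation), while fbp1a, a gluconeogenic phosphatase, rose by 0.43 (SE 0.08). Skeletal muscle, exocrine pancreas and endothelium lists did not pass (camera adjusted p = 0.324, 0.121 and 0.768), and tek, an endothelial receptor gene, rose by 0.75 (SE 0.12). Of 46 constitutive proteasome genes, 4 rose and 3 fell, 6 adjusted over the list alone (camera adjusted p = 0.698).

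The cardiac-type actin gene actc1c fell by 6.76 in the glo1 knockout (SE 0.37), from 88.9 ± 29.8 to 0.814 ± 0.271 CPM (SD, n = 5 each). The chaperone regulator ahsa1 (ENSDARG00000028664) fell by 2.85 (SE 0.25), and fkbp15a rose by 2.17 (SE 0.21). The double knockout, which also lacks glo1, had both actc1c and this ahsa1 copy far higher than the glo1 knockout, as given below. Neither fall was thus seen at this size in both genotypes without glo1. Of 22234 genes, 7286 passed the edgeR test, 3253 higher and 4033 lower. With a change of at least 1 on the log2 scale, 236 were higher and 746 lower. Camera called 15 lists, 7 higher and 8 lower, and 0 with an estimated correlation, against 16 by fry.

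The third comparison concerned the double knockout, the subject of the series title. It combined lower liver genes with higher lens genes. Of 39 liver genes, 38 fell and 1 rose, 39 adjusted over the list alone (median -1.47, camera adjusted p = 1.34e-16; adjusted p = 0.784 with an estimated correlation). The largest falls included c3a.2, a complement gene (-2.84, SE 0.30), gc, the vitamin D binding protein gene (-2.79, SE 0.28), and fgg, a fibrinogen gene (-2.60, SE 0.27). Lens genes rose in 48 of 57 cases and fell in 1, with 49 adjusted over the list alone (median 0.95, camera adjusted p = 3.44e-16; adjusted p = 0.795 with an estimated correlation). Exocrine pancreas genes fell in 21 of 29 cases and rose in 1, with 23 adjusted over the list alone (median -1.19, camera adjusted p = 0.00294; adjusted p = 0.795 with an estimated correlation), and enterocyte and lipid transport genes fell in 25 of 33 cases and rose in 0, with 26 adjusted over the list alone (median -1.20, camera adjusted p = 1.19e-05; adjusted p = 0.795 with an estimated correlation). Ribosomal protein genes rose in 79 of 90 cases and fell in 4, with 83 adjusted over the list alone (median 0.54, camera adjusted p = 2.60e-36; adjusted p = 0.757 with an estimated correlation). The 79 genes of very long proteins had a median of -0.12 against 0.08, with 27 lower and 9 higher. Of 13 mitochondrially encoded genes, 9 rose and 1 fell, with 10 adjusted over the list alone (camera adjusted p = 0.00142; adjusted p = 0.795 with an estimated correlation), and their share of counts was 3.47% ± 0.156 (SD, n = 5).

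On the topics of the title, gluconeogenesis and glycogen genes fell in 21 of 33 cases and rose in 3 in the double knockout, 25 adjusted over the list alone (camera adjusted p = 0.00878; adjusted p = 0.795 with an estimated correlation), with fbp1a higher by 0.82 (SE 0.08) and ugp2 (ENSDARG00000005578), which makes UDP-glucose, lower by 1.56 (SE 0.21). The glycolysis list (camera adjusted p = 0.956), the insulin and glucose transport list (0.161), the endocrine pancreas list (0.949) and the endothelium list (0.620) did not pass. Of 42 insulin signalling and glucose transport genes, 17 fell and 5 rose, 23 adjusted over the list alone (median -0.07, mean -0.32), and fry, which does not compare the list with other genes, called the list lower (adjusted p = 9.86e-05). Its mean log2 CPM relative to wild type was -0.46 to -0.21 in the double knockout libraries and -0.06 to 0.09 in the wild type libraries. Of 69 endothelium and angiogenesis genes, 17 rose and 14 fell, 31 adjusted over the list alone, with a median of 0.12 and a mean of -0.03. Of 46 constitutive proteasome genes, 8 rose and 13 fell, 21 adjusted over the list alone, and the list did not pass (median -0.02, camera adjusted p = 0.670). Both psmd2 copies fell, ENSDARG00000103190 by 1.66 (SE 0.12) and ENSDARG00000099653 by 0.61 (SE 0.07). The edgeR test passed 11190 genes, 5319 higher and 5871 lower, and with a change of at least 1 on the log2 scale 462 higher and 2065 lower. Camera called 12 lists, 5 higher and 7 lower, and 0 with an estimated correlation, against 19 by fry.

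Set against the aldh3a1 knockout, the double knockout had higher muscle and lens genes. Skeletal muscle genes were higher in 58 of 74 cases and lower in 2, with 62 adjusted over the list alone (median 0.66, camera adjusted p = 4.55e-36; adjusted p = 0.268 with an estimated correlation), and lens genes in 48 of 57 with 0 lower and 48 adjusted over the list alone (camera adjusted p = 3.63e-29; adjusted p = 0.268 with an estimated correlation). Of 46 proteasome genes, 10 were lower and 0 higher, 10 adjusted over the list alone (median -0.10, camera adjusted p = 0.000823; adjusted p = 0.587 with an estimated correlation). The mitochondrially encoded list was called lower (camera adjusted p = 0.00179, or 0.542 with an estimated correlation). Its means relative to wild type were 0.29 in the double and 0.50 in the aldh3a1 knockout. Besides the targeted glo1 (-4.19, SE 0.09), the largest fall among the genes named by the rule was that of tnfrsf14 (-4.35, SE 0.34), and the largest rise was that of actc1c (2.41, SE 0.27). The edgeR test passed 5039 genes, 2458 higher and 2581 lower, and with a change of at least 1 on the log2 scale 454 were higher and 93 lower.

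Set against the glo1 knockout, the double knockout had actc1c higher by 6.54 (SE 0.37) and ahsa1 (ENSDARG00000028664) higher by 2.91 (SE 0.25), and the heat shock gene hsp70l lower by 2.36 (SE 0.52). Ribosomal protein genes were higher in 65 of 90 cases and lower in 2, with 76 adjusted over the list alone (camera adjusted p = 9.54e-25; adjusted p = 0.970 with an estimated correlation). Of 39 liver genes, 6 were lower and 0 higher, with 9 adjusted over the list alone (camera adjusted p = 4.91e-07; adjusted p = 0.970 with an estimated correlation). The edgeR test passed 2521 genes, 1004 higher and 1517 lower. This count depended on single libraries: it was 1331 without glo1 knockout replicate 5, 1302 without double knockout replicate 4 and 1451 without double knockout replicate 5.

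The interaction asked whether both losses together differed from the sum of each. Liver and skeletal muscle genes were less low in the double knockout than the sum of both single changes. The skeletal muscle list mean relative to wild type was -0.80 in the aldh3a1, -0.10 in the glo1 and -0.23 in the double knockout. A difference of the wild type libraries from all others would also give an interaction opposite in sign to the single changes. The design cannot tell this apart from an effect of both losses together. Liver genes had a positive interaction in 32 of 39 cases and a negative one in 0, with 35 adjusted over the list alone (median 1.14, camera adjusted p = 1.57e-10; adjusted p = 0.437 with an estimated correlation). Skeletal muscle genes had a positive one in 56 of 74 cases and a negative one in 3, with 59 adjusted over the list alone (camera adjusted p = 7.18e-18; adjusted p = 0.437 with an estimated correlation). Ribosomal protein genes, higher in both single knockouts, had a negative one in 72 of 90 cases and a positive one in 2, with 77 adjusted over the list alone (camera adjusted p = 5.68e-21; adjusted p = 0.437 with an estimated correlation). The mitochondrially encoded list was called as well (camera adjusted p = 1.53e-05, or 0.437 with an estimated correlation). Its means relative to wild type were 0.50 in the aldh3a1, 0.20 in the glo1 and 0.29 in the double knockout. Among the genes named by the rule, the interaction was largest for actc1c (9.17, SE 0.47). Constitutive proteasome genes had a negative interaction in 11 of 46 cases and a positive one in 3, with 14 adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.697 with an estimated correlation), a call lost without aldh3a1 knockout replicate 3 (adjusted p = 0.0635) or wild type replicate 5 (adjusted p = 0.0725). The neurons and synapse list was called lower (camera adjusted p = 0.0399; adjusted p = 0.697 with an estimated correlation) with a median of -0.15 and a mean of 0.01. That call was lost, with adjusted p from 0.0572 to 0.107, without replicate 1, 2 or 3 of the aldh3a1 knockout, 3 or 5 of the glo1 knockout, 3 of the double knockout or 4 of wild type. In all 7905 genes passed, 4157 positive and 3748 negative, and with an interaction of at least 1 on the log2 scale 1617 were positive and 223 negative.

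Across the single knockouts, 6226 genes were called in the same direction, 2636 higher and 3590 lower, and 122 in opposite directions. Both comparisons used the same wild type libraries. Over 20 simulations of unchanged groups, the overlap was 0 on average, a value for groups without any effect, which does not measure how the shared libraries act on lists with real effects. Independent lists of these sizes would share 955 higher and 1290 lower genes. With the wild type libraries split between the comparisons, 3516 genes were shared, and 4447 with the same libraries assigned the other way round. The covariance of log2 fold changes across genes, which are not independent replicates, was 0.259 against 0.0205 simulated and 0.232 with split controls. Both parts of the split keep any difference of the wild type libraries from all others. The overlap and the covariance thus do not separate it from a change shared by the knockouts.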

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

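The tests of regrouped libraries, long genes and abundant genes were chosen after the results were seen. The tests of genes near the edited loci were written before.

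The interaction, a test of whether the aldh3a1 loss acts differently with and without glo1, passed for 7905 genes. A difference of the wild type libraries from all others would enter the interaction too. Among the named genes it was 9.17 for actc1c, 4.64 for ggact (ENSDARG00000038248), 4.32 for ahsa1 (ENSDARG00000028664), 3.81 for scg5 (ENSDARG00000077045) and 3.46 for kcna7. It was -3.14 for tnfrsf14, -2.59 for ctsb, -2.52 for hsp70l, -1.77 for scg5 (ENSDARG00000032126) and -1.69 for hsp70.1. The ggact value depended on 1 library: without glo1 knockout replicate 1 it was 8.47 (edgeR adjusted p = 4.29e-06), a fitted value against libraries near 0.

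One library stood apart from the other 4 of its genotype in 18 of 341 combinations of a printed gene and genotype, 5.28%, and over all genes named by the rule in 48 of 818, 5.87%. Chance gives about 1 in 20, or 5%. In wild type these were actc1c in replicate 5 (36.6 CPM, the others 93.8 to 108.1), ahsa1 (ENSDARG00000028664) in replicate 5 (2.58 CPM), atp2a2a in replicate 5 (25.2 CPM), dnmt3a (ENSDARG00000005394) in replicate 2 (10.5 CPM), evi5l in replicate 4 (3.69 CPM), rpl39 in replicate 4 (925 CPM) and tiparp in replicate 3 (45.4 CPM). In the aldh3a1 knockout they were cdh15 in replicate 1 (0.707 CPM) and cfh in replicate 3 (1.15 CPM). In the glo1 knockout they were ggact (ENSDARG00000038248) in replicate 1 (2.56 CPM, the others 0 to 0.142) and scg5 (ENSDARG00000077045) in replicate 4 (2.32 CPM). In the double knockout they were crygm2d3 in replicate 4 (810 CPM), crygm2d5 in replicate 4 (236 CPM), fabp7 (ENSDARG00000034650) in replicate 2 (1.27 CPM), fkbp15a in replicate 2 (12.8 CPM), scg5 (ENSDARG00000032126) in replicate 3 (16.8 CPM), scg5 (ENSDARG00000077045) in replicate 4 (15.4 CPM) and tcap in replicate 3 (167 CPM).

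Random groupings of the same libraries give a measure of chance. For gene counts, the real grouping was the single one of 100 splits with a count as large in each comparison. For the comparisons between genotypes, counts this large are thus unlikely from a random assignment of these libraries. A difference between clutches, pools or batches would also set the real grouping apart, and the splits cannot exclude it. For the interaction a random assignment cannot be excluded, because all genotype labels were shuffled there, which also mixes the single effects. The highest other counts were 7317 against 13637 in the aldh3a1 knockout, 640 against 7286 in the glo1 knockout, 2878 against 11190 in the double knockout, 679 against 5039 and 6 against 2521 in the double knockout set against the aldh3a1 and glo1 knockouts, and 5555 against 7905 for the interaction. For the numbers of lists chance could not be excluded. A count as large came from 44 of 100 splits for the aldh3a1 knockout (16 real, highest other 23), 41 for the glo1 knockout (15, highest other 23), 70 for the double knockout (12, highest other 23), 25 against the aldh3a1 knockout (17, highest other 24), 85 against the glo1 knockout (6, highest other 21) and 6 for the interaction (20, highest other 22). Camera with a preset correlation therefore called lists in libraries mixed at random, and the list calls in the report rest on that setting. Mixing a pair of genotypes with 5 libraries each is always uneven, so part of the genotype difference can remain in a split. The splits are thus no clean measure of chance for list calls.

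The breadth of the change in the aldh3a1 knockout, 13637 of 22234 genes, has technical candidates. A few abundant genes taking up reads would move all other genes by 1 common factor, and as the whole cause this is argued against by large changes in both directions: of the genes that changed by at least 1 on the log2 scale, 512 were higher and 3040 lower. A loss of reads from long transcripts stays open. Only 79 of 108 listed genes of very long proteins were matched, 73.2%, under the 80% set for the check, so it was treated as void. The prediction as written held no such condition and was met. The median of -0.11 lay under 0.05, the 2.5th percentile of the random lists. Those lists were matched on expression alone, so other traits of the genes, such as their tissue, were not accounted for. As a description, 35 of the 79 were lower and 12 higher, with a median log2 fold change of -0.11 against 0.14 for 10000 random lists matched on expression, of which 0 were as low; in the glo1 knockout the medians were -0.07 against 0.06 and in the double knockout -0.12 against 0.08, again with 0 as low. Clutch, age and library batch are not given apart from genotype in the labels and were not tested, so a biological cause was not separated from these.

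Calls near the edited genes might reflect linked variants. In the glo1 knockout 31.7% of 161 neighbours of glo1 were called against 32.1% of other genes (Fisher's exact test, one-sided p = 0.571), an odds ratio of 0.982 with a 95% interval of 0.689 to 1.384. In the aldh3a1 knockout 57% of 200 neighbours of aldh3a1 were called against 61.3%, an odds ratio of 0.836 with an interval of 0.625 to 1.121 (Fisher's exact test, one-sided p = 0.907). No excess of calls was found, and the intervals leave a small excess open.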

How the results depend on the processing

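The wild type split and the other alternatives were planned before the data were examined. The rule gave 500 gene values. All kept their side of the threshold under the other scaling factors, DESeq2, limma-voom, no filter and no robust estimation. So did 494 of 494 under the stricter filter, 499 under the replicate block and 485 of 488 in fits on the compared genotypes alone. With any library left out, 5079 of 5110 kept their side, 30 lost the call and 1 gained it. In all these fits, 0 values that passed in the main fit reversed. The glo1 interaction, which did not pass, changed sign in some fits (-0.0058, and 0.042 with upper-quartile factors). Apart from glo1, the genes were named because they passed, so this stability was largely set by the choice of genes. Requiring a change of at least 1 on the log2 scale left 3552 genes in the aldh3a1, 982 in the glo1 and 2527 in the double knockout against wild type, 547 and 292 in the double knockout against the aldh3a1 and glo1 knockouts, 1840 in the interaction and an overlap of 713. These fewer genes follow from the added threshold. With an estimated correlation, camera called 0 lists in all 6 comparisons. By fry, 19 lists were called in the double knockout against wild type and 1 against the glo1 knockout; fry asks a different question, and the cause was not tested beyond that. Splitting the wild type libraries left an overlap of 3516, with fewer controls per comparison.

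With 1 library left out, calls ranged from 12847 to 13663 for the aldh3a1 knockout, 5831 to 6978 for the glo1 knockout and 10175 to 11203 for the double knockout against wild type. They ranged from 3479 to 4973 and from 1302 to 2271 against the aldh3a1 and glo1 knockouts, and from 6926 to 8417 for the interaction. Against the glo1 knockout the count was 1331 without glo1 knockout replicate 5, 1302 without double knockout replicate 4 and 1451 without double knockout replicate 5. Lists called ranged from 13 to 16, 13 to 19, 11 to 13, 12 to 18, 4 to 7 and 18 to 23 in the order of the report, and the overlap from 4962 to 6250.

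The replicate numbers did not pair the samples: same-numbered libraries correlated above 0.1 in 5 of 30 pairs (from -0.163 to 0.253). In 8 of the 30 pairs the same-numbered library was the best match within the other genotype. With the replicate block, calls were 13511, 7097, 11039, 4878, 2602 and 7820 in the same order. The block lost 1 list call, neurons and synapse in the interaction (camera adjusted p = 0.0579). It raised the lists called from 17 to 18 in the double knockout against the aldh3a1 knockout. Upper-quartile factors moved the higher share of calls from 47.9% to 42.6% in the aldh3a1 knockout. In simulation of the glo1 comparison over 22234 genes, with 50 genes changed at each fold, 10% of genes changed 1.2-fold were recovered. The adjusted threshold is stricter with few changed genes, so this is no measure of recovery where 7286 genes passed.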

Other observations

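The test of the proteasome parts was chosen after the values were seen, and psmd4, psmc6, psmd3, psma6l and psmb6 were named for it outside the naming rule, after their values were seen.

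Genes of nuclear-encoded oxidative phosphorylation, which code for parts of the respiratory chain, rose in 48 of 113 cases and fell in 1 in the glo1 knockout, with 51 adjusted over the list alone (camera adjusted p = 2.50e-07; adjusted p = 0.597 with an estimated correlation). In the double knockout 53 rose and 12 fell, with 70 adjusted over the list alone (camera adjusted p = 0.000726; adjusted p = 0.795 with an estimated correlation). The list was also called higher in the aldh3a1 knockout (camera adjusted p = 0.0344, or 0.883 with an estimated correlation). That call was lost with upper-quartile factors (camera adjusted p = 0.0810). It was also lost without wild type replicate 5 (camera adjusted p = 0.161) or aldh3a1 knockout replicate 5 (camera adjusted p = 0.0774). Neuron and synapse genes fell in 28 of 61 cases and rose in 11 in the double knockout, with 40 adjusted over the list alone (camera adjusted p = 0.00492; adjusted p = 0.795 with an estimated correlation). Xenobiotic metabolism genes fell in 28 of 48 cases and rose in 5 in the aldh3a1 knockout, with 33 adjusted over the list alone (camera adjusted p = 0.00195; adjusted p = 0.600 with an estimated correlation).

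The constitutive proteasome list did not pass in the double knockout. Of its 23 genes of the regulatory particle, which recognises and unfolds substrates, 12 were lower and 1 higher. Of 16 genes of the proteolytic core particle, 0 were lower and 3 higher, and 7 genes of the list belong to neither part. The medians were -0.14 and 0.04. The lower genes included psmd7 (-0.68, SE 0.09), psmd4 (-0.46, SE 0.10), psmc6 (-0.29, SE 0.07) and psmd3 (-0.26, SE 0.06), and the higher core genes were psma1 (0.32, SE 0.05), psma6l (0.55, SE 0.19) and psmb6 (0.17, SE 0.05). A hypothesis is that transcripts of the regulatory particle may be lower relative to those of the core. Fisher's exact test of lower calls gave a two-sided p of 0.000372, or 0.00112 adjusted over the 3 comparisons with wild type, but since the split was found on these values, the p describes it and is no independent evidence. The same test gave 0.0660 in the aldh3a1 knockout (5 of 23 against 0 of 16 lower, 5 against 10 higher), where the medians of -0.02 and 0.15 lay about as far apart. It gave 0.255 in the glo1 knockout (3 of 23 against 0 of 16 lower, 1 against 2 higher; medians -0.04 and 0.07). Whether the knockouts differ in this respect was not tested. Members of one complex are not independent, and several regulatory subunits are larger proteins than the core subunits, so a loss of reads from longer transcripts stays open, as does the hypothesis. Transcript levels do not measure proteasome activity.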
